A study of Mus musculus with 143 samples.

How the data were processed

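Brain sections of 5 female C57BL/6 mice aged 28 months were profiled with the GeoMx mouse Whole Transcriptome Atlas, a panel of hybridization probes whose tags are released by light from a masked area and sequenced. Per the labels, the 5 µm paraffin sections came from hemispheres fixed in 4% paraformaldehyde for 24 hours. Each of the 143 segments carries a mouse, a region and a mask. The masks were IBA1 (a microglial protein), Galectin-3, both proteins together, and SYTO83 nuclear stain alone. The labels do not say whether the IBA1 and Galectin-3 masks exclude the area positive for both.

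The deposited values are deduplicated counts per probe, with no normalization. Per the file headers, the authors ran the GeoMx NGS Pipeline 2.3.3.10, which trims and stitches reads, aligns them to the probe tags and collapses them by unique molecular identifier. The submitters' processing notes name the build GRCm39. The headers also give raw and aligned reads, from which the aligned share and the sequencing saturation of each segment were computed. No pair of segments had identical counts (0 pairs).

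The files identify probes by code and do not pair the codes with genes. The reference table, which lists 49997 genes of assembly GRCm38.p6, held 0 of the 20175 probe codes. The 13 function lists and 9 cell type lists (423 gene symbols) fixed beforehand, the marker check of the masks and the background from negative probes were therefore not run. Negative probes could not be told from the others by code, so any called probe may be one. All results concern probes, and at most 2 codes that rose and 2 that fell are printed.

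A segment entered with at least 1000 counts and 50% saturation, and segments of the same mouse, region and mask were summed. A sum entered with at least 5000 counts, so the mouse was the replicate. Tests used edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) with TMM scaling, library totals over all probes, filterByExpr at a minimum count of 10, and the mouse as a block. Benjamini-Hochberg adjusted p under 0.05 counted as a call. A fit of 28 sums in 7 groups and 237 probes served the comparisons among IBA1, Galectin-3 and double-masked sums. Another fit of 27 sums in 6 groups and 866 probes served the comparisons of IBA1 with SYTO83. Their common dispersions were 0.0667 and 0.0399, and their TMM factors ran from 0.673 to 2.61 and from 0.714 to 1.47. The tested probes held a median of 3.04% and 9.51% of a sum's counts.

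The regional difference of IBA1 against SYTO83 was not among the comparisons fixed beforehand. The other comparisons, the thresholds, the alternatives and the rule for named items were fixed before the data were examined. That rule took the largest rises and falls, up to 12 each way in the 2 lead comparisons and 5 each way in the others. It required a call, a mean log2 CPM (counts scaled to the library total) above the median of tested probes, and the same direction in every mouse with both groups. Because no names could be attached, only its leading rise and fall in the longest list are given by code. A further probe was chosen after its values were seen. Differences of single values were tested with exact two-sided sign-flip permutation tests over the mice, 9 in all. Intervals for pooled shares are exact Clopper-Pearson intervals at the 95% level, and a count of 0 was taken to allow up to 3 counts. Both cover counting error only.

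The alternatives fixed at that stage were DESeq2 1.42.0, upper-quartile scaling, no count filter, only the groups compared, no mouse block, segments as observations (limma 3.58.1, voom with duplicateCorrelation), stricter and looser count minimums, at least 75% of reads aligned, only areas holding both masks, library plate added to the block, and each mouse left out. Alternatives added after the data were seen were scaling by total counts, removal of probes high in a single segment, the log2 aligned share as a covariate beside the block, removal of probes that followed the aligned share, and each plate alone. Mice N101 and N108 were on plate A only, N112 was on plate B only, and N110 and N111 were on both. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

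The fits were tested on simulated data with known changes. Apart from these changes, all simulated sums of a fit were drawn from 1 pooled probe profile with 1 common dispersion. No mouse differences and no probes high in a single segment were put in. There, 324 and 780 probes were tested, against 237 and 866 in the real data. The recovery and false calls hold for that simpler setting and may not carry over to the real data. Only changed probes that passed the count filter again in the simulated counts are counted below, 55 and 128 in the 2 comparisons. Further changed probes did not pass it and could not be found. In the comparison of double-masked with IBA1 sums in the fimbria, edgeR found 2 of 13 probes changed 1.5-fold, 9 of 19 changed 2-fold and 23 of 23 changed 4-fold, with 0 false calls. For IBA1 against SYTO83 it found 3 of 40, 25 of 43 and 45 of 45, with 6 false calls. DESeq2 found 2, 12 and 22 in the former comparison, with 3 false calls, and 3, 22 and 45 in the latter, with 4. Mouse pairing came from mice that gave both groups of a comparison; not every mouse gave every group. After group means were removed, sums of the same mouse correlated with a mean r of 0.143 between double-masked and IBA1 fimbria sums and 0.145 between IBA1 and SYTO83 fimbria sums, against -0.0325 and -0.0356 between different mice. The mean r was lower in the other pairs tested: 0.0178 against -0.00127 for IBA1 sums of fimbria and hippocampus, and 0.0579 against -0.0127 for IBA1 and SYTO83 hippocampus sums. Because group means were removed, the values between different mice are tied to those of the same mouse. They are therefore not an independent reference for the pairing.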

Results

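The data are probe counts from 143 masked segments of 4 brain regions in 5 aged mice, named N101, N108, N110, N111 and N112. The fimbria, a white matter tract, gave 20 IBA1, 20 double-masked (IBA1 and Galectin-3), 17 Galectin-3 and 18 SYTO83 segments. The hippocampus gave 19, 7, 6 and 15 segments in the same order. The cortex gave 6 IBA1, 4 double-masked and 5 SYTO83 segments, and the anterior commissure gave 6 segments from a single mouse.

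In all, 3873965 counts were spread over 20175 probes. Of the 143 segments, 122 passed the minimums, 18 had fewer than 1000 counts and 3 more failed on saturation. Passing segments held 1699 to 196736 counts with a median of 19510, which is 0.967 counts per probe. The median depth was 28194 counts for IBA1, 22688 for SYTO83, 11937 for double-masked and 4794 for Galectin-3 segments. The share of reads that aligned to probe tags ran from 1.53% to 95.5%, with medians of 78.7%, 73.5%, 46.2% and 23.2% in the same order. Of the segments under 1000 counts, 6 of 80 were on plate A and 12 of 63 on plate B. The 12 include all 6 anterior commissure segments, a region that was on plate B only and held at most 333 counts per segment.

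**Figure D1:**
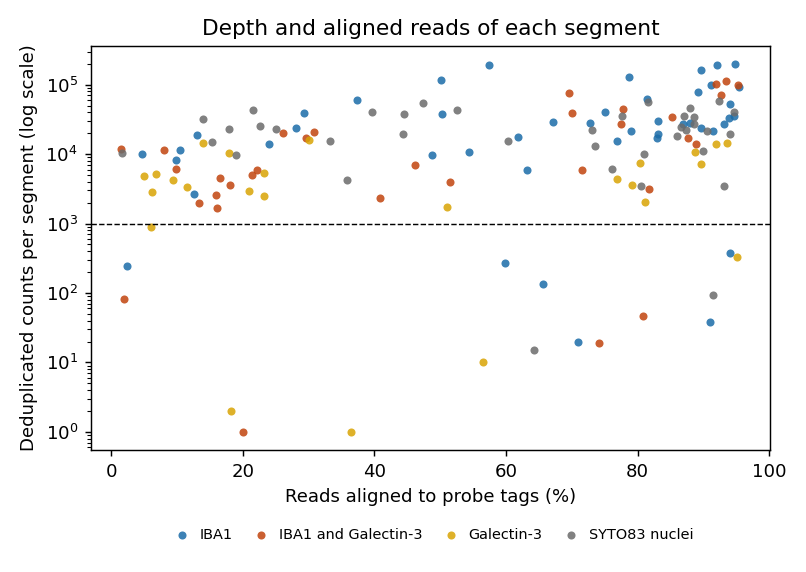
Deduplicated counts of each segment (log scale; the segments without counts are left out) against the percentage of its reads aligned to probe tags, coloured by mask. The dashed line marks the minimum of 1000 counts, and the median aligned share was 78.7% for IBA1 and 23.2% for Galectin-3 segments that passed.

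The first comparison asked how microglia that carry Galectin-3 differ from IBA1 area of the same white matter; the labels do not say whether the IBA1 mask leaves out area positive for Galectin-3. In the fimbria, the probe RTS0080776 was higher in double-masked than in IBA1 sums by 2.02 log2 units (SE 0.35, edgeR adjusted p = 2.02e-05) and was higher in 5 of 5 mice. It took 3.50 ± 2.15 (SD, n = 5 mice) of every 10000 counts in double-masked sums and 0.694 ± 0.503 (SD, n = 5 mice) in IBA1 sums. Nuclear SYTO83 sums of the fimbria held 0.422 ± 0.358 per 10000 (SD, n = 5 mice). The values rest on 153, 31 and 14 counts of the probe, respectively, and the probe was chosen after its values were seen. If all probes took an even share, 100 probes would hold 0.496% of counts, or 0.496 per 10000 for each. The IBA1 and SYTO83 levels lay near that share, and no background from negative probes was available to set against them. Of the 237 probes tested, 2 were called higher and 0 lower by edgeR, 9 had an unadjusted p under 0.05, and DESeq2 called 1 probe, higher. The second called probe was higher by 2.90 log2 units (SE 0.67, edgeR adjusted p = 0.00414) in 3 of 5 mice, and a single N101 segment held 1079 of its counts against 279 in all other segments. The mean difference of RTS0080776 was 2.81 ± 1.69 per 10000 (SD, n = 5 mice), with an exact sign-flip permutation p = 0.0625, the smallest that 5 mice allow, and 0.141 after adjustment over 9 such tests. Without N101 or without N111, 1 probe was called. Among segments of plate A alone RTS0080776 was higher by 2.21 log2 units (edgeR adjusted p = 0.0214), and among those of plate B alone by 1.90 (edgeR adjusted p = 0.255).

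**Figure D2:**
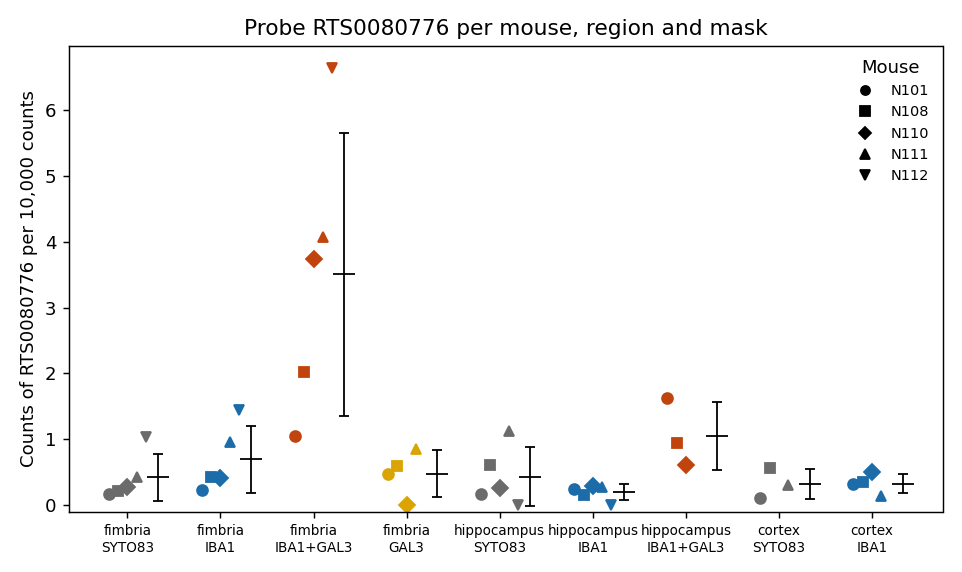
Counts of probe RTS0080776 per 10000 counts for each mouse (marker shape) in 9 groups of region and mask, with the mean and SD at the right of each group. Double-masked fimbria sums averaged 3.50 against 0.694 in IBA1 sums of the fimbria.

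The same contrast in the hippocampus asked whether Galectin-3 marks a like difference outside the tract. There, double-masked sums exceeded IBA1 sums for 2 of 237 probes and fell below them for 0 in edgeR. The increases were 2.15 (SE 0.57) and 1.78 (SE 0.48) log2 units, both with an edgeR adjusted p = 0.0363 and both in 3 of 3 mice, 17 probes had an unadjusted p under 0.05, and DESeq2 called 0. RTS0080776 took 1.05 ± 0.519 per 10000 (SD, n = 3 mice) in double-masked and 0.195 ± 0.121 (SD, n = 5 mice) in IBA1 hippocampus sums. These levels rest on 5 of 60600 and 31 of 1208060 counts, respectively. The fold of RTS0080776, 1.16 log2 units (SE 0.83), did not pass the test (edgeR adjusted p = 0.776). The probe was higher in 3 of 3 mice, but the 3 double-masked sums held only 5 of its counts together. The called pair rested on hippocampal double-masked sums of 6165 to 33091 counts, and 0 probes were called without N101, without N108, without N110 or without N112. With upper-quartile scaling, without the count filter, with only the 2 groups compared or on plate A alone, 0 were called as well. More were called with plate added to the block or with segments as observations. The median aligned share was 14.3% in these sums and 58.2% in the IBA1 sums; with that share as a covariate the folds were 1.89 (SE 0.63) and 1.30 (SE 0.51) log2 units, smaller and with wider errors, and 0 probes were called. Scaled by total counts, 4 probes were called higher and the median of all tested probes moved from -0.23 to 0.37 log2 units.

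The contrast of fimbria against hippocampus was itself tested. The difference between double-masked and IBA1 sums depended on the region for 1 probe. Its fold was lower in the fimbria by -2.37 log2 units (SE 0.59, edgeR adjusted p = 0.0267), with the same direction in 3 of 3 mice. It is the probe called higher by 1.78 log2 units in the hippocampus contrast. The same probe was called higher in fimbria Galectin-3 than double-masked sums, by 2.33 log2 units, so these calls are not separate findings. Counts of this probe fell as the aligned share rose in IBA1 and SYTO83 segments, and with that share as a covariate the difference was -2.02 (SE 0.60, edgeR adjusted p = 0.266), smaller with a wider error, and 0 probes were called. DESeq2 called 0 probes and 14 had an unadjusted p under 0.05 in edgeR. For RTS0080776 the difference between regions was 0.87 log2 units (SE 0.84, edgeR adjusted p = 0.821). The called difference was absent without N101 or without N108, where 0 probes passed, without N110 a different probe passed, 2 passed without N111, and scaling by total counts gave 4 lower probes with a median of -0.22 instead of 0.23. Without the count filter, without the mouse block, with segments as observations, without the probes that followed the aligned share or on plate A alone, 0 probes were called. In the cortex the 3 double-masked sums held 3564, 3964 and 4585 counts, under the minimum of 5000, so no value was computed at the planned setting.

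Region comparisons asked whether microglia of white matter differ from those of grey matter. Among IBA1 sums, edgeR called 0 of 237 probes between fimbria and hippocampus (n = 5 and 5 mice) and 0 between fimbria and cortex (n = 5 and 4 mice). At an unadjusted p under 0.05 the counts were 10 and 5, and DESeq2 called 0 in each. Without N108 or N110 the former comparison called 1 and 3 probes, and without N110 the latter called 1. With at least 75% aligned reads the former called 7 and the latter 1. The former called 2 without the count filter, with the stricter count minimums or on plate A alone.

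Double-masked sums of the fimbria exceeded those of the hippocampus for 4 of 237 probes (n = 5 and 3 mice). Among them RTS0065961 was higher by 2.13 log2 units (SE 0.61, edgeR adjusted p = 0.0392) in 3 of 3 mice, at 4.08 ± 0.991 per 10000 (SD, n = 5 mice) against 1.03 ± 0.950 (SD, n = 3 mice). That hippocampus level rests on 8 of 60600 counts, with 0 of 6165 in N101. Of the other called probes, 2 had only 2 counts each in the hippocampus sums, and the ratios of their pooled shares were 5.96 (exact interval of counting 1.62 to 49.7) and 7.17 (1.95 to 59.7). The last, higher by 3.24 log2 units (SE 0.89, edgeR adjusted p = 0.0386), is the probe that stood out in a single N101 segment and had 6 counts in the hippocampus sums. In all, 21 probes had an unadjusted p under 0.05, and DESeq2 called 0. Scaling by total counts moved the median from 0.22 to -0.25 log2 units and gave 0 higher and 4 lower probes, of which 0 were shared. Without N101, N108, N110 or N112 the calls numbered 1, 0, 1 and 2. Without the count filter or on plate A alone 0 were called, and with only the 2 groups compared 2 were, of which 0 were shared. Plate added to the block and segments as observations each gave more calls. The median aligned share was 29.3% in fimbria and 14.3% in hippocampus sums; with it as a covariate 1 probe was called, and the fold of RTS0065961 was 2.06 (SE 0.62, edgeR adjusted p = 0.0945).

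Area under the Galectin-3 mask was also compared with double-masked area of the fimbria; the labels do not say whether that mask leaves out IBA1-positive area. RTS0080776 was lower in Galectin-3 sums by -2.24 log2 units (SE 0.59, edgeR adjusted p = 0.0122) in 4 of 4 mice, at 0.480 ± 0.356 per 10000 (SD, n = 4 mice). That level rests on 5 counts of 99399, and the N110 sum held 0 of 21091 counts, which allows up to 1.42 per 10000. Another 5 probes were higher by 1.87 to 2.69 log2 units, and 2 of them were higher in 4 of 4 mice. The 5 include both probes called higher in double-masked than IBA1 sums of the hippocampus. For 1 of the 5, higher by 2.06 log2 units (SE 0.47), a single N110 segment held 24 of its 31 counts in Galectin-3 fimbria sums. In all, edgeR called 5 of 237 probes higher and 1 lower, 20 had an unadjusted p under 0.05, and DESeq2 called 4 higher and 0 lower. Without N110, 0 probes passed, and without N108 only 1 other probe passed. A fit of only the 2 groups compared, in which 11 probes could be tested, and plate A alone gave 0 calls each. Segments as observations gave more calls. With segments of at least 75% aligned reads alone, 0 passed and 3 of the 5 folds changed sign. With all passing segments and the aligned share as a covariate, 5 of the 6 calls were kept and no other was added; the fold of RTS0080776 was then -2.42 log2 units (SE 0.61, edgeR adjusted p = 0.00752), and the lost probe had 1.75 (SE 0.53, edgeR adjusted p = 0.0559).

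Pooled counts of 4 probes, those called higher in Galectin-3 sums of the fimbria or double-masked sums of the hippocampus and not high in a single segment, moved with the aligned share. Fimbria Galectin-3 segments under 25% aligned held 21 per 10000 (exact interval 16.8 to 25.9, n = 6 segments) and those at 75% or more held 4.55 (2.74 to 7.11, n = 6 segments). Of the 19 pooled counts in the latter, 10 lay in a single N110 segment of 3546 counts, and the other 5 segments held 2.36 per 10000 (1.08 to 4.47). In double-masked fimbria segments the levels were 10.3 per 10000 (6.26 to 15.8, n = 3 segments) and 1.73 (1.39 to 2.13, n = 9 segments). In fimbria IBA1 segments the levels were 25 per 10000 (18.6 to 33, n = 2 segments) and 1.78 (1.42 to 2.20, n = 10 segments).

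**Figure D3:**
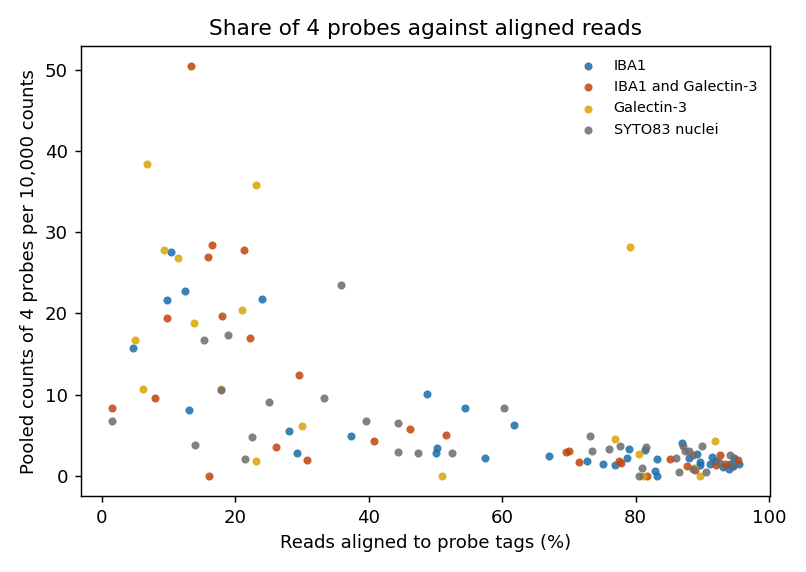
Pooled counts of the 4 probes per 10000 counts in each passing segment against the percentage of reads aligned to probe tags, coloured by mask. The pooled share was 21 per 10000 in fimbria Galectin-3 segments under 25% aligned and 4.55 in those at 75% or more, or 2.36 without the 1 N110 segment that held 10 of their 19 pooled counts.

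Microglial area was set against nuclear-stained area to show what the IBA1 mask enriches. In the fimbria, IBA1 sums exceeded SYTO83 sums for 21 of 866 probes and fell below them for 24 (edgeR, n = 5 and 5 mice). The probe RTS0065961 was higher by 1.44 log2 units (SE 0.29, edgeR adjusted p = 8.59e-04) in 5 of 5 mice, at 3.88 ± 1.05 per 10000 (SD, n = 5 mice) in IBA1 and 1.84 ± 1.40 (SD, n = 5 mice) in SYTO83 sums. The probe RTS0067278 was lower by -1.34 log2 units (SE 0.32, edgeR adjusted p = 0.00351) in 5 of 5 mice, at 0.830 ± 0.449 against 2.27 ± 0.365 per 10000 (SD, n = 5 mice each). The 21 higher probes had folds of 1.07 to 1.53 log2 units and 14 of them were higher in every mouse; the 24 lower ones ran from -1.34 to -0.89 and 21 were lower in every mouse. Lower probes were also the more abundant, with a median of 7.84 log2 CPM against 6.89 for higher probes and 6.85 for all tested.

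In this comparison 188 probes had an unadjusted p under 0.05, and DESeq2 called 19 higher and 13 lower. Scaling by total counts gave 3 higher and 137 lower, with the median of tested probes at -0.45 instead of -0.00 log2 units, so the split between directions depended on the scaling. Calls numbered 7 without N101, 28 without N108, 12 without N110 and 74 without N112. Without the mouse block, 16 probes were called. Plate A alone gave 23 calls and plate B alone 0.

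**Figure D4:**
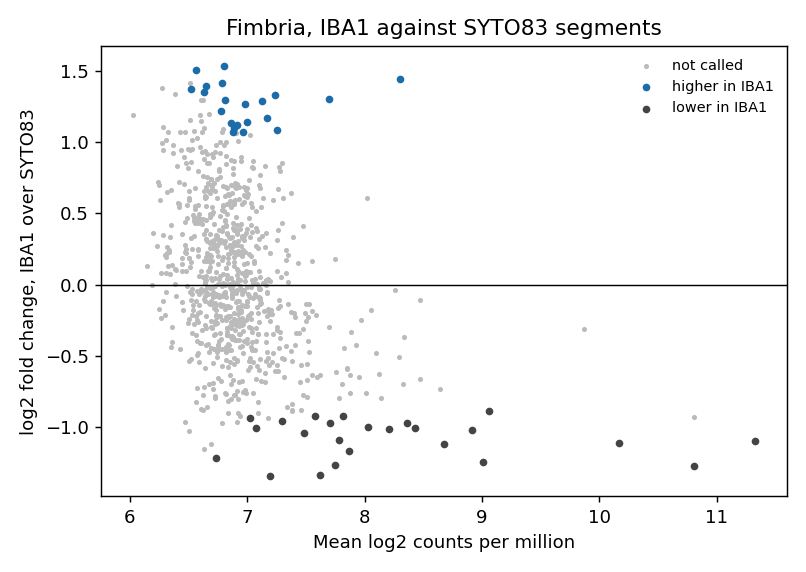
Log2 fold change of IBA1 over SYTO83 fimbria sums against mean log2 CPM for 866 probes, with the 21 probes called higher and the 24 called lower marked. Lower probes had a median abundance of 7.84 and higher probes of 6.89 log2 CPM.

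In the hippocampus the IBA1 sums fell below SYTO83 sums for 1 probe, by -2.08 log2 units (SE 0.31, edgeR adjusted p = 3.32e-08) in 4 of 5 mice, and exceeded them for 0. A single N101 segment held 51 of the 80 counts of this probe in hippocampus SYTO83 sums. There, 42 probes had an unadjusted p under 0.05, DESeq2 called 0, and without N101 the probe was not called. Nor was it with only the 2 groups compared, with segments as observations, with the stricter count minimums, with at least 75% aligned reads or on either plate alone. In the cortex 1 probe was higher by 3.29 log2 units (SE 0.71, edgeR adjusted p = 0.00287) and 1 lower by -2.20 (SE 0.51, edgeR adjusted p = 0.00659), each in 3 of 3 mice, and DESeq2 called 1 higher. The higher probe rests on 33 counts in cortex IBA1 sums and 4 of 190247 in SYTO83 sums. The lower probe rests on 9 of 220776 counts in cortex IBA1 sums and 48 in SYTO83 sums. RTS0065961 was higher in IBA1 sums by 0.95 log2 units (SE 0.34, edgeR adjusted p = 0.560) in the hippocampus and by 0.35 (SE 0.38, edgeR adjusted p = 0.754) in the cortex. Scaling by total counts gave 1 higher and 23 lower probes in the cortex, with the median at -0.45 instead of -0.04 log2 units, and 0, 1, 1 and 1 probes were called without N108, N101, N110 and N111. With segments as observations or the stricter count minimums 0 were called there, and neither called probe was among the calls with only the 2 groups compared or with at least 75% aligned reads.

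The difference between fimbria and hippocampus in this contrast was not among the comparisons fixed beforehand. It was called for 1 probe, higher by 2.3 log2 units (SE 0.52, edgeR adjusted p = 0.00935) in 5 of 5 mice. That probe is the 1 called in the hippocampus, where N101 alone held 8.94 per 10000 in SYTO83 sums against 2.55 in the next mouse. A single N101 segment held 51 of its 80 counts in those sums. Without N101 or without N111, 0 probes were called, and 2 without N108. Without the count filter, with segments as observations, with the stricter count minimums, with at least 75% aligned reads, scaled by total counts or on either plate alone, 0 were called. In this test 58 probes had an unadjusted p under 0.05 and DESeq2 called 0.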

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

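All tests of explanations in this part, and the counts of splits, were chosen after the results were seen.

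The clearest difference of the Galectin-3 contrast was the rise of RTS0080776 in double-masked fimbria area. A low aligned share of reads as the whole cause is argued against by the fold of 1.90 log2 units (SE 0.36, edgeR adjusted p = 2.18e-04) with that share as a covariate, beside 2.02 without it. The same holds for a single segment, since leaving out any 1 of the 35 fimbria segments left at least 1.93 log2 units and an adjusted p of at most 4.80e-04. Library plate in the fit left 2.08 (SE 0.36). A higher level of this probe in fimbria area masked for both proteins remains open as a hypothesis. The probe has no gene name here and could be a negative probe, so it is not known to measure a transcript. The masks were not checked by markers, so what the cells are and express could not be followed further.

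The 4 probes that were higher in Galectin-3 fimbria or double-masked hippocampus sums, and were chosen for being so, were pooled over segments, with a difference of 2.32 log2 units (SE 0.57) between Galectin-3 and double-masked fimbria segments. Trends were fitted over 74 IBA1 and SYTO83 segments that share 5 mice, with a term per mouse and errors over segments. There the pooled share changed by -0.67 log2 units (SE 0.10) per doubling of the aligned share and by -0.58 (SE 0.11) per doubling of counts, so each may account for part of the difference. With the aligned share in the model 1.56 log2 units (SE 0.40, jackknife error over mice 0.955) were left, but 0.50 (SE 0.36) without N110; with counts 1.01 (SE 0.45, jackknife error 0.237), but 0.87 (SE 0.53) without N111, 0.94 (SE 0.51) without N108 and 1.01 (SE 0.55) without N110. With both, 1.0 (SE 0.36, jackknife error 0.554) were left, but 0.37 (SE 0.36) without N110, so a low aligned share, low counts per segment and the pair of them all stay open as the whole cause. A difference of the cells under the Galectin-3 mask stays open and untested, and cannot be told apart from these, because with a mouse left out the remainder came within 2 errors of 0.

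The 100 probes with the most counts in the other regions took 2.37 ± 1.03% of counts in IBA1 fimbria sums and 4.42 ± 1.06% in SYTO83 sums (SD, n = 5 mice each), lower in 5 of 5 mice with an exact sign-flip p = 0.0625, the smallest possible. An even share of all probes would be 0.496%. Over 33 segments that share 5 mice, in a model with a term per mouse and errors over segments, the difference of -0.99 log2 units (SE 0.10) stayed at -0.996 (SE 0.10) with the aligned share in the model, and the median fold fell with abundance over the 9 lower deciles too (rank correlation -0.983), which argues against a few abundant probes as the whole cause. Even background over all probes is a candidate explanation that the rank correlation of -0.988 over all 10 deciles is consistent with. Different cells under the masks, which the design names, would also change these shares, and that was not tested because the probes have no gene names.

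Splits of the same sums into groups of the same sizes were counted for every test across probes, and each count of splits below includes the real one. For double-masked against IBA1 sums of the fimbria, chance cannot be excluded for the count, since 9 of 100 splits called as many as the real 2, with 2 as the highest other. It cannot for the regional difference of the Galectin-3 contrast (25 of 100 splits, real 1, highest other 2), for hippocampus IBA1 against SYTO83 (58 of 100 splits, real 1, highest other 3), for cortex (3 of 35 splits, real 2, highest other 4) or for the regional difference of IBA1 against SYTO83 (31 of 100 splits, real 1). In the last case another split called 43 probes; it kept the masks of all 10 fimbria sums and of 6 of 10 hippocampus sums, so it carried the fimbria difference between the masks. For the IBA1 comparisons of fimbria with hippocampus and with cortex the real count was 0, which all 100 splits must reach, so the splits decide nothing there (highest other 1).

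In 4 comparisons the share among all splits was under 0.05: fimbria IBA1 against SYTO83 (1 of 100 splits, real 45, highest other 13), fimbria Galectin-3 against double-masked sums (3 of 100, real 6, highest other 7), the hippocampus Galectin-3 contrast (1 of 56, real 2, highest other 1) and double-masked sums of fimbria against hippocampus (2 of 56, real 4, highest other 4). Most of those splits ignore the mouse pairing, and splits that part as many mouse pairs as the real one are the closer comparison. Among these, again with the real one included, 2 of 15 gave as many for Galectin-3 against double-masked sums, with 7 as the highest other, and 2 of 8 for double-masked sums of fimbria against hippocampus, with 4, so chance is not excluded for either. For fimbria IBA1 against SYTO83 the 13 such splits are too few for a share under 0.05 (real 45, highest other 10), as are the 8 for the hippocampus Galectin-3 contrast (real 2, highest other 1).

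Single mice stood far from the others in 7 of 38 groups of values, where chance gives about 1 in 20; most of these are values of probes chosen for being called, to which that rate does not strictly apply. In double-masked fimbria sums, 1 probe took 46.0 per 10000 counts in N101 against 0.873 in the next mouse. Another took 8.85 in N112 against 2.04 in the next, from a sum of 9039 counts. RTS0065961 took 2.33 in N111, below 4.32 in the next mouse. In Galectin-3 fimbria sums 1 probe took 11.4 in N110 against 1.19. In hippocampus SYTO83 sums 1 probe took 8.94 in N101 against 2.55. In cortex IBA1 sums 1 probe took 1.15 in N111 against 0.157, and the 100 leading probes took 2.07% in N111 against 1.62%.

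The 2 effects that differed between fimbria and hippocampus by an interaction term were those of 1 probe in the Galectin-3 contrast, at -2.37 log2 units, and of 1 probe in the contrast with SYTO83, at 2.3. Each of these probes is also among those with a single distant mouse, but the distant values act differently. For the Galectin-3 contrast it was N112 in double-masked fimbria sums, at 8.85 per 10000 against 2.04 in the next mouse. That high value raises the fimbria fold, against the called direction. For the contrast with SYTO83 it was N101 in hippocampus SYTO83 sums, at 8.94 against 2.55. That value goes with the called direction, and the call ended without N101. The regional comparison in the contrast with SYTO83 was not among those fixed beforehand. Counts outside the comparisons were 791 in the 6 anterior commissure segments, 12113 in the 4 double-masked cortex segments and 23695 in the 6 Galectin-3 hippocampus segments. These are totals over all 20175 probes, and the anterior commissure total was smaller than the number of probes.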

How the results depend on the processing

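Scaling by total counts, removal of probes by either criterion, the aligned share as a covariate and single plates were alternatives chosen after the data were seen, and the others were chosen before. Depth limited every comparison: passing segments had a median of 0.967 counts per probe, and 237 and 866 of the 20175 probes could be tested. RTS0080776 in the fimbria kept its direction in all 22 alternatives run and its call in 21 of them, with log2 folds from 1.78 to 2.25 and adjusted p up to 0.255; plate B alone ended the call, with fewer mice and 91 probes tested. RTS0065961 was called higher in IBA1 than SYTO83 fimbria sums in 19 of 22 alternatives (0.91 to 1.98), and RTS0067278 lower in 18 of 21 (-1.91 to -0.97). Counts of called probes moved by more than 1.5 times in 114 cases, given here or as ranges, and stayed within that in the other cases. Single probes kept their direction and call in 237 cases, kept the direction alone in 136 and reversed in 3. The reversals all came with at least 75% aligned reads, in fimbria Galectin-3 against double-masked sums, at -0.22, -0.24 and -0.49 log2 units. Stricter minimums left no value for any comparison with hippocampus double-masked or fimbria Galectin-3 sums, the aligned minimum none for hippocampus double-masked sums, and plate B alone none for hippocampus double-masked or cortex sums. Areas holding both masks apply to mask comparisons only. The negative-probe background, the gene lists and their set tests were not run, since no probe could be matched to a gene. Except where fewer mice, segments or probes entered, the cause of a change was not tested.

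Counts of called probes under the alternatives chosen beforehand that moved them were as follows. DESeq2 called 0 for hippocampus double-masked against IBA1, the regional difference of double-masked against IBA1, double-masked fimbria against hippocampus, hippocampus IBA1 against SYTO83 and the regional difference of IBA1 against SYTO83, and 1 for fimbria double-masked against IBA1 and cortex IBA1 against SYTO83. Only the 2 groups compared gave 0 for hippocampus double-masked against IBA1, fimbria Galectin-3 against double-masked and hippocampus IBA1 against SYTO83, and 1 for fimbria double-masked against IBA1. There were also 2 for double-masked fimbria against hippocampus. Segments as observations (limma voom) gave 0 for the regional difference of double-masked against IBA1, cortex IBA1 against SYTO83 and the regional difference of IBA1 against SYTO83, and 1 for fimbria double-masked against IBA1. It also gave 2 for hippocampus IBA1 against SYTO83, 8 for fimbria IBA1 against SYTO83, 9 for hippocampus double-masked against IBA1, 10 for double-masked fimbria against hippocampus and 14 for fimbria Galectin-3 against double-masked. Looser count minimums gave 1 for fimbria double-masked against IBA1, and 4 for the regional difference of double-masked against IBA1. A minimum of 75% aligned reads gave 0 for fimbria Galectin-3 against double-masked, hippocampus IBA1 against SYTO83 and the regional difference of IBA1 against SYTO83, and 1 for fimbria double-masked against IBA1, IBA1 fimbria against cortex and cortex IBA1 against SYTO83. There were also 7 for IBA1 fimbria against hippocampus and fimbria IBA1 against SYTO83. Plate added to the mouse block gave 1 for fimbria double-masked against IBA1, and 2 for the regional difference of IBA1 against SYTO83. It also gave 4 for the regional difference of double-masked against IBA1, 6 for hippocampus double-masked against IBA1 and 7 for double-masked fimbria against hippocampus. Upper-quartile scaling gave 0 for hippocampus double-masked against IBA1, and 2 for hippocampus IBA1 against SYTO83. Without a filter on low counts there were 0 for hippocampus double-masked against IBA1, the regional difference of double-masked against IBA1, double-masked fimbria against hippocampus and the regional difference of IBA1 against SYTO83, and 1 for cortex IBA1 against SYTO83. There were also 2 for IBA1 fimbria against hippocampus, 3 for fimbria Galectin-3 against double-masked, 5 for hippocampus IBA1 against SYTO83 and 119 for fimbria IBA1 against SYTO83. Only areas holding both masks gave 1 for hippocampus double-masked against IBA1 and cortex IBA1 against SYTO83, and 17 for fimbria IBA1 against SYTO83. The fit without a replicate block gave 0 for the regional difference of double-masked against IBA1, and 2 for double-masked fimbria against hippocampus. It also gave 16 for fimbria IBA1 against SYTO83. Stricter count minimums gave 0 for cortex IBA1 against SYTO83 and the regional difference of IBA1 against SYTO83, and 2 for IBA1 fimbria against hippocampus.

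Among the alternatives added later, the counts that moved were these. Removal of probes high in 1 segment gave 0 for hippocampus IBA1 against SYTO83 and the regional difference of IBA1 against SYTO83, and 1 for fimbria double-masked against IBA1. There were also 2 for the regional difference of double-masked against IBA1. Plate B alone gave 0 for fimbria double-masked against IBA1, fimbria IBA1 against SYTO83, hippocampus IBA1 against SYTO83 and the regional difference of IBA1 against SYTO83, and 2 for fimbria Galectin-3 against double-masked. Scaling by total counts gave 0 for the regional difference of IBA1 against SYTO83, and 4 for hippocampus double-masked against IBA1 and the regional difference of double-masked against IBA1. It also gave 24 for cortex IBA1 against SYTO83 and 140 for fimbria IBA1 against SYTO83. The aligned share as a covariate beside the replicate block gave 0 for hippocampus double-masked against IBA1 and the regional difference of double-masked against IBA1, and 1 for double-masked fimbria against hippocampus. It also gave 10 for cortex IBA1 against SYTO83. Removal of probes that followed the aligned share gave 0 for the regional difference of double-masked against IBA1, and 1 for hippocampus double-masked against IBA1. Plate A alone gave 0 for hippocampus double-masked against IBA1, the regional difference of double-masked against IBA1, double-masked fimbria against hippocampus, fimbria Galectin-3 against double-masked, hippocampus IBA1 against SYTO83 and the regional difference of IBA1 against SYTO83, and 2 for IBA1 fimbria against hippocampus. It also gave 4 for cortex IBA1 against SYTO83 and 23 for fimbria IBA1 against SYTO83.

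Leaving out each mouse in turn gave 1 to 2 for fimbria double-masked against IBA1, 0 to 2 for hippocampus double-masked against IBA1, 0 to 2 for the regional difference of double-masked against IBA1, and 0 to 3 for IBA1 fimbria against hippocampus. The same step gave 0 to 1 for IBA1 fimbria against cortex, 0 to 3 for double-masked fimbria against hippocampus, and 0 to 6 for fimbria Galectin-3 against double-masked. For nuclei as the reference it gave 7 to 74 for fimbria IBA1 against SYTO83, 0 to 2 for cortex IBA1 against SYTO83, and 0 to 2 for the regional difference of IBA1 against SYTO83. The lowest fimbria count against SYTO83 came without N101 and the highest without N112.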

Other observations

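Correlations, leading-probe tests, trends with the aligned share and counts of probes high in 1 segment were chosen after the data were seen; the double-masked cortex values are alternatives fixed before. The contrast of IBA1 with SYTO83 area was most similar between fimbria and cortex. Over 866 probes, its log2 folds in these regions correlated with r = 0.533 (Spearman 0.540), or 0.471 given mean abundance. The fimbria and hippocampus folds correlated less, with r = 0.281 (Spearman 0.257), or 0.238 given mean abundance, and hippocampus and cortex with r = 0.207 (Spearman 0.184). These are correlations across probes, which are not independent replicates. Of the 45 probes called in the fimbria, 42 had the same direction in the cortex and 37 in the hippocampus, against 621 and 492 of all 866.

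The share of the 100 leading probes, those with the most counts in the other regions, was lower in IBA1 than in SYTO83 sums in each region. In the cortex it was 1.71 ± 0.238% (SD, n = 4 mice) against 3.43 ± 0.335% (SD, n = 3 mice), lower in 3 of 3 mice with an exact sign-flip p = 0.25, the smallest possible. In the hippocampus it was 2.03 ± 0.516% against 3.03 ± 0.926% (SD, n = 5 mice each), lower in 4 of 5 mice with an exact sign-flip p = 0.188. Double-masked and IBA1 fimbria sums differed by 0.0522 ± 0.504 percentage points (SD, n = 5 mice), with an exact sign-flip p = 0.875. Galectin-3 fimbria sums held 1.70 ± 0.472% (SD, n = 4 mice).

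Some probes differed between the mice themselves. After group effects, edgeR called 3 of 237 probes in the fit of the microglial masks and 21 of 866 in the fit with nuclei as different among the 5 mice, and 28 and 88 had an unadjusted p under 0.05.

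Galectin-3 sums of the hippocampus entered with 2 mice and no comparison. RTS0065961 took 3.18 ± 0.574 per 10000 counts there (SD, n = 2 mice). RTS0080776 had 0 of 21963 counts, which allows up to 1.37 per 10000. The 6 anterior commissure segments, from a single mouse, held 10 to 333 counts each. With looser minimums, double-masked cortex sums differed from IBA1 cortex sums for 4 probes higher and 10 lower of 82 tested, with a median of -0.83 log2 units. With segments as observations in limma voom, 2 were higher and 9 lower of 30. The median aligned share was 16.9% in the double-masked and 71.1% in the IBA1 cortex segments, so these differences may reflect that share.

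In 74 IBA1 and SYTO83 segments, 63 probes were tested for a trend with the aligned share of reads. The segments share 5 mice, and the fit had a term per mouse with errors over segments, so the segments are not independent replicates. By edgeR, 4 fell with it and 0 rose, and 9 had an unadjusted p under 0.05. Pairs of a probe and a segment with at least 20 counts and 8 times the probe's usual share numbered 30. They came from 29 probes in 20 segments, so not every such probe was high in a single segment only.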
